A study of Pseudomonas aeruginosa PAO1 with 8 samples.

How the data were processed

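Total RNA was sequenced from cultures of Pseudomonas aeruginosa PAO1, a laboratory reference strain, kept in liquid M9, a defined minimal salts medium, at 30 °C. Cultures were exposed for 2 h to silver in the form of AgNP at 1, 20 or 25 mg/L or of AgNR at 1, 30 or 300 mg/L. The labels give only these abbreviations, which are read here as silver nanoparticles and silver nanorods. There were 8 libraries in 7 groups: 1 control without silver, 1 library at each dose, and 2 libraries at AgNP 25 mg/L. Both series share the single control. The labels do not state whether the 2 AgNP 25 libraries came from separate cultures, so every p-value below measures only the spread between those libraries, or the scatter around a dose line.

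The deposited table gave FPKM, a measure of fragments scaled by gene length and by the mapped fragments of the library, for 5697 genes in 8 columns, per the file headers. The submitters' processing notes name Cufflinks 2.2.1. The aligner, the annotation release, the strand setting, the scaling between libraries and the read numbers are not given in the sources used here. Column medians lay between 39.6 and 42.9 FPKM. The control and the AgNP 25 columns held values as a quantification tool prints them. The other 5 columns appear to have been recomputed by the authors with a formula that held a division, and their unit is FPKM by header only. In these 5 columns all 88 genes listed at 0 in the control held a division error, 0 other genes did, and 99.7 to 99.9% of the values carried more than 6 digits. A formula that put each gene on the scale of the listed control would give this pattern, but the formula was not stated. Under such a formula, an error in the control value of a gene would recur in the recomputed columns. The genes at 0 in the control included all 76 rRNA and tRNA genes, and these 88 genes were left out, which left 5609 genes with 8 values.

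Genes were matched to RefSeq names by locus tag (3932 genes), by symbol (1763) or by coordinates (2), with 0 unmatched. Positions are 1-based on the single PAO1 chromosome, with position 1 taken as the replication origin, in the coordinates of the deposited table, and refer to annotated genes, which in bacteria have no introns. FPKM depends on the assigned length, and 1576 genes shared a merged locus with an overlapping neighbour. Fragments in such loci can be credited to either gene, and the strand setting is unknown, so values of genes in shared loci are uncertain. Values of genes under 200 nt, of which 78 were measured, depend strongly on the effective length that the authors' tool used. Near-identical copies, such as the 2 phenazine operons, are likewise uncertain. Depth is unknown, because the table holds no counts, and no counting interval or detection floor can be given. A low percentile of neighbouring genes, used below as a local background, had a median of 27.5 FPKM in the control. It was 26.4 and 26.1 FPKM in the AgNP 25 pair. The size of a change that starts or ends near or below such values is therefore uncertain. The precision seen is that of the AgNP 25 pair, whose log2 values differed with an SD of 0.30 across genes.

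Values were transformed as log2(FPKM + 1), and genes with a mean of at least 5 FPKM over the 8 libraries were tested, 5608 in all. Fits were made with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. All limma tests were two-sided. The dose fit had 1 shared intercept, 1 slope per log2(1 + dose in mg/L) for AgNP and 1 for AgNR, with 5 residual degrees of freedom. The group fit had 1 mean per group and 1 residual degree of freedom, which came from the AgNP 25 pair, moderated with 17.3 prior degrees of freedom. It assumes that the lone control and the lone AgNR 30 library vary as that pair does. Comparisons of single libraries had no test. For these, genes were counted that differed at least 2-fold with a value of at least 10 FPKM in either library.

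There were 29 gene lists, tested on the dose fit with camera from limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The median change of a list was also ranked among 10000 random lists matched on mean expression in 20 bins, and the percentile says how many random lists lay lower. The comparisons, gene lists, thresholds and first set of alternatives were fixed before the data were examined. So was the rule for named genes: the 10 largest rises and 10 largest falls of each main comparison, the 5 largest each way of other comparisons, and the 4 members of each list with the largest change, taken in order and sometimes shortened. Genes named outside this rule are said to be so.

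The alternatives fixed in advance were a pseudocount of 0.1 or 10, no filter or a mean of at least 20, rescaling by the median ratio to the gene-wise geometric mean, quantile normalization, moderation without a trend, dose as a rank, each series alone, only the 2 groups compared, AgNP 20 and AgNP 25 pooled, and each library left out in turn. Added after the data were seen were removal of a local background, taken as the 10th percentile of genes of at least 300 nt within 100 kb, with a pseudocount of 10 and a mean of at least 20 left; removal of the running median of the fold in a 200 kb window along the chromosome; and exclusion of genes under 200 nt. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. The fits were tested on simulated data with known changes. In the AgNP 25 against control design, 26% of genes changed by 0.5 log2 units were recovered, 90% of those changed by 1, and 100% of those changed by 2. In each simulation 200 of 5608 genes were changed. Among the genes left unchanged, 14 were called in that design, 7 for the AgNP trend and 5 for the slope difference. These false calls came beside true ones and are not counts for data without any change. For the AgNP slope, 19.4% of genes with a slope of 0.25 and 82.1% of those with 0.5 were recovered.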

Results

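The series measured the transcriptome of P. aeruginosa PAO1 after 2 h with silver nanoparticles (AgNP) or silver nanorods (AgNR), to compare the response to the particle forms and to rising doses. The 8 libraries comprised 1 control, 1 library each at AgNP 1, AgNP 20, AgNR 1, AgNR 30 and AgNR 300 mg/L, and 2 at AgNP 25 mg/L. Expression was given as FPKM. The depth of each library is unknown. Only AgNP 25 had 2 libraries, so values from the control and every other group stand for 1 library without a replicate.

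Library medians were alike, from 39.6 FPKM in AgNR 30 and AgNR 1 to 42.9 FPKM in AgNP 25 replicate 2, while the spread of values among genes was not. The middle 50% of genes spanned 0.81 log2 units in the control, 0.90 to 1.07 in the 3 AgNR libraries, 1.54 and 1.57 in the AgNP 25 pair, 1.83 in AgNP 1 and 2.78 in AgNP 20. In the control 90% of genes lay between 21.2 and 139 FPKM, and in AgNP 20 between 5.78 and 975 FPKM. Genes with high mean expression therefore had a higher median change against the control than other genes, and random lists of the same expression are given for the gene lists at AgNP 25 for that reason.

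**Figure D1:**
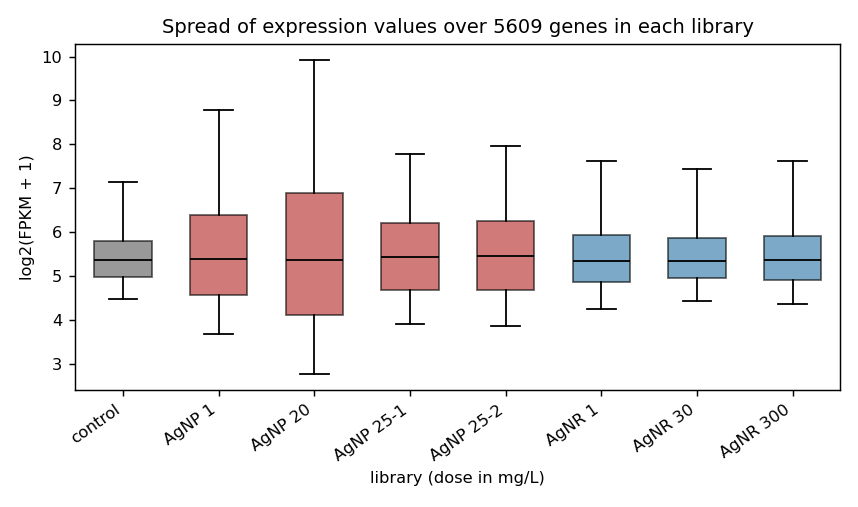
Log2(FPKM + 1) of 5609 genes (vertical axis) in each of the 8 libraries (horizontal axis, dose in mg/L), with boxes for the middle 50% of genes, lines at medians and whiskers to the 5th and 95th percentiles. The box of the control is the narrowest, at 0.81 log2 units, and that of AgNP 20 the widest, at 2.78.

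The comparison of AgNP 25 with the control asked which genes respond to the highest particle dose. The genes that rose most belonged to Pf4, a filamentous prophage carried in the PAO1 chromosome, to metal export and to iron storage. The phage coat protein gene coaB (PA0723, positions 790986 to 791234) rose from 165 FPKM in the control to 16061 and 21461 FPKM in the AgNP 25 pair, a log2 change of 6.80 (SE 0.22, n = 2 against 1). PA3574a, annotated as the copper chaperone CopZ (4007127 to 4007324), rose from 27.2 to 2835 and 2786 FPKM, a log2 change of 6.64. PA3920, a metal-transporting P-type ATPase (4389231 to 4391609), rose from 41.7 to 1965 and 2024 FPKM, and bfrB (PA3531, 3950284 to 3950760), which encodes the iron storage protein bacterioferritin, from 37.0 to 1036 and 1144 FPKM. Their log2 changes were 5.55 (SE 0.18) and 4.84 (SE 0.18).

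In the Pf4 list 10 of 13 measured members rose and 0 fell, with a median log2 change of 4.84 against 0.81 for random lists of matched expression. Besides coaB, PA0720, PA0719, PA0722 and PA0718 rose by log2 6.77, 6.32, 5.79 and 5.76. The 9 measured genes from PA0718 to PA0727 rose by at least log2 4.67, whereas the 4 genes at the ends of the prophage had log2 changes between -0.01 and 0.80. Of the 21 genes of the copper and silver export list, 10 rose and 1 fell, with a median of 0.52 against -0.09 for matched lists. PA3920 was followed by ptrA, annotated as a repressor (3.58), PA3523, a membrane fusion protein of an efflux pump (3.24), and PA2807 (2.53). The list for zinc and cadmium efflux gave 2 rises and 4 falls among 10 members, and its largest change was that of PA3690, another metal-transporting P-type ATPase, with log2 2.83. Its list median was -0.26, against -0.33 for matched lists, and 0.04 among the 7 members with a mean of at least 20 FPKM, where that of the copper list was 0.89. PA3574a and PA3523 share loci with neighbours, and PA3574a and ptrA are under 200 nt, which makes their FPKM uncertain.

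Genes of both siderophores, the secreted iron chelators of this species, fell together. All 11 pyochelin genes fell, with a median log2 change of -2.37 against 0.39 for matched random lists. The pyochelin synthesis gene pchB (PA4230) fell from 515 to 19.5 and 32.9 FPKM, a log2 change of -4.29 (SE 0.24), the receptor gene fptA had -3.09 and pchA had -2.93. All 18 pyoverdine genes fell, with a median of -1.16 against -0.44 for matched lists. They were led by pvdS, the sigma factor of pyoverdine synthesis, which fell from 256 to 17.3 and 22.6 FPKM, a log2 change of -3.63 (SE 0.21), and by pvdA with -2.63. Of the 24 genes for quorum sensing, the cell density signalling of this species, 14 fell and 0 rose, with a median of -0.76 against -0.23 for matched lists. The regulator gene rsaL had a log2 change of -3.77, the rhamnolipid synthesis gene rhlA -2.78 and the regulator gene lasR -2.26. The genes pchB, pchA, fptA, rsaL and lasR lie in loci shared with neighbours.

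Stress defence and central metabolism genes moved mostly upward. In the list for oxidative stress defence 11 of 20 genes rose and 4 fell, with a median of 0.63 against 0.31 for matched lists (percentile 94.3). The catalase gene katA rose from 82.2 to 547 and 649 FPKM, a log2 change of 2.84 (SE 0.18), ahpC had 2.29 and the superoxide dismutase gene sodB 2.05, whereas sodM, the other superoxide dismutase gene, fell from 271 to 46.8 and 50.3 FPKM (-2.46). Of 10 genes for the SOS response to DNA damage, 8 rose and 0 fell, led by recA with 2.53 and recN with 2.32. The SOS median of 0.69 lay near the 0.53 of matched random lists. Ribosomal protein genes rose in 48 of 54 cases, with rpsF at 2.55 and rplI at 2.46. Their median was 1.38 and that of matched lists 1.03, at percentile 99.2. The list includes 1 gene that is not a ribosomal protein, PA4672 for peptidyl-tRNA hydrolase. In the list for the TCA cycle and glyoxylate shunt 16 of 18 genes rose and 0 fell, among them glcB (2.41), aceA (2.21) and sucD (2.01), and the median of 1.22 lay above the matched 0.62, at percentile 99.6. Quantile normalization lowered the ribosomal median to 0.61, with 35 rises and 5 falls, and that for oxidative stress from 0.63 to 0.18. Removal of a local background raised the SOS median to 1.12. It took that of quorum sensing from -0.76 to -2.53 among the 9 of 24 members left. That of copper and silver export went to 2.87 among the 11 of 21 members left. The median of all genes left was itself 0.29 and 0.37 in the AgNP 25 pair. The filter on the mean of all libraries can also keep genes because they are high with AgNP.

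Genes for growth at low oxygen moved both ways. The Anr list, named after the regulator of that response, gave 8 rises and 2 falls among 14 genes, led by the arginine deiminase pathway genes arcB (2.70), arcA (2.64) and arcC (2.57). Iron-sulfur cluster assembly gave 6 rises among 8, led by iscS (2.13), with a median of 0.78 against 0.80 for matched lists. NADH dehydrogenase and ATP synthase gave 10 rises and 1 fall among 22 genes, led by atpA (102 to 454 and 495 FPKM), and terminal oxidases 7 rises and 2 falls among 13. Heat shock genes rose in 7 of 16 cases, fell in 1, and were led by dnaK (1.22). Against matched lists the medians were 1.07 and 0.66 for Anr (percentile 95.9), 0.35 and 0.46 for NADH dehydrogenase and ATP synthase (27.2), 0.51 and 0.01 for terminal oxidases (98.1) and 0.39 and 0.58 for heat shock (19.5). In the denitrification list 12 of 33 genes rose and 3 fell, among them nirM with 2.65 and napE with -2.14. Of 37 pyocin genes, which encode phage tail-like bacteriocins, 17 rose and 3 fell, with the activator gene prtN at 2.29. The medians of these last 2 lists, 0.23 and 0.39, lay below the matched 0.61 and 1.03, at percentiles 2.69 and 0.065. After quantile normalization they turned to -0.38 and -0.51, with 13 and 21 falls. It lowered the medians of heat shock from 0.39 to 0.02, of iron-sulfur assembly to 0.31, of terminal oxidases from 0.51 to 0.24 and of Anr from 1.07 to 0.30, and raised that of NADH dehydrogenase and ATP synthase from 0.35 to 0.58. Heat shock then had 1 rise and 3 falls. Removal of a local background raised the NADH dehydrogenase and ATP synthase median to 0.93, where all genes left had medians of 0.29 and 0.37 in the pair. The genes sucD and nirM share loci with neighbours.

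Several lists changed along with their place on the chromosome. At AgNP 25 the change against the control was highest near the replication origin and lowest opposite it, with slopes of -0.470 and -0.471 log2 units per Mb of distance in the pair. AgNP 1 and AgNP 20 had slopes of -0.39 and -0.45 log2 units per Mb, and the 3 AgNR libraries between -0.08 and 0.04. All 18 genes of the H1 type VI secretion cluster, a contractile injection apparatus, lie a median 0.10 Mb from the origin and rose, with a median of 0.95. The phosphate starvation list, at 0.23 Mb, gave 7 rises and 0 falls among 10 genes (median 0.96). The Zur list for zinc uptake, at 0.84 Mb, gave 11 rises and 2 falls among 25 (0.47). The Psl and Pel exopolysaccharide list, at 2.47 Mb, gave 12 falls and 0 rises among 19 (-0.61), and 2 falls with a median of -0.22 after quantile normalization. The Zur median was 0.75 among members with a mean of at least 20 FPKM. Matched lists had medians of 0.22, 0.04, 0.00 and -0.47 for these 4 lists. With the running median of the fold along the chromosome removed, the 4 lists had 0 calls and medians of -0.03, -0.01, 0.04 and -0.06. After the same removal 10 Pf4, 44 ribosomal and 16 TCA genes were called up, and 11 pyochelin, 6 pyoverdine and 8 quorum sensing genes down. The pyoverdine median was then -0.41 and that of quorum sensing -0.23. The removal turned the denitrification median to -0.07, with 7 rises and 5 falls, and that of the pyocins to -0.01, with 5 rises and 6 falls. The zinc and cadmium efflux median was then -0.02 with 2 rises, that of oxidative stress defence 0.12 with 6 rises and 1 fall, and that of heat shock 0.20 with 3 rises. Terminal oxidases had 3 rises and SOS 5. The NADH dehydrogenase and ATP synthase median rose from 0.35 to 0.61, with 12 rises and 0 falls. It lay at percentile 100 of random lists of the same size. Those lists were not matched on expression, so this percentile cannot be set against the 27.2 of matched lists before the removal.

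**Figure D2:**
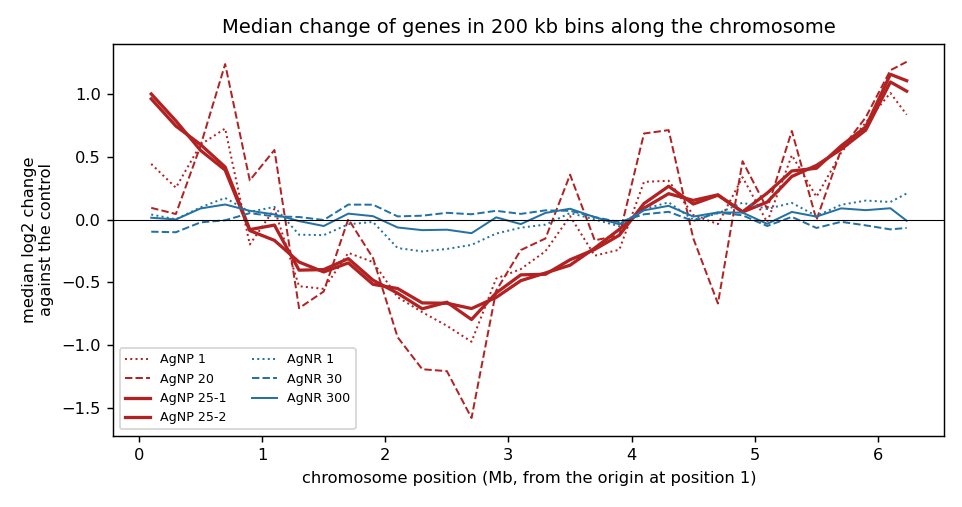
Median log2 change against the control (vertical axis) of the genes in bins of 200 kb along the chromosome (horizontal axis, Mb), 1 line per silver library. The bold AgNP 25 lines are highest at both ends of the map, next to the origin, and lowest near its middle, with slopes of -0.470 and -0.471 log2 units per Mb of distance, whereas AgNP 1 and AgNP 20 had slopes of -0.39 and -0.45 and AgNR 300 of -0.03.

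The remaining lists gave calls in both directions or in few members. Type III secretion gave 1 rise and 12 falls among 39 genes, the flagellum 4 rises and 8 falls among 42, and type IV pili 5 rises and 0 falls among 24. Multidrug RND efflux gave 7 rises and 2 falls among 30, lipopolysaccharide modification 2 rises and 0 falls among 16, alginate synthesis 2 rises and 0 falls among 12, and phenazine synthesis 1 rise and 1 fall among 17. The list for sulfate, sulfonate and cysteine assimilation gave 9 rises and 5 falls among 22, with the largest change in PA3441 (-2.14). Rescaling by the median ratio left 1 rise and 7 falls in type III secretion, and 6 rises and 3 falls in sulfur assimilation. The medians against matched lists were -0.48 and -0.51 for type III secretion (percentile 66.9), -0.07 and 0.26 for the flagellum (0.38), 0.28 and 0.42 for pili (20.7) and 0.15 and -0.09 for RND efflux (97.4). They were -0.09 and 0.32 for lipopolysaccharide modification (1.74), 0.24 and 0.05 for alginate synthesis (87.7), -0.08 and -0.19 for phenazine synthesis (75.5) and -0.05 and 0.31 for sulfur assimilation (1.81). In the 2 AgNP 25 libraries taken singly, lipopolysaccharide modification had medians of 0.03 and -0.12, sulfur assimilation -0.17 and 0.06, and pili 0.10 and 0.43. Quantile normalization turned the type III median from -0.48 to 0.01 and that of pili from 0.28 to -0.13. It turned lipopolysaccharide modification to 0 rises and 3 falls (median -0.09 to -0.35) and sulfur assimilation to 3 rises and 9 falls (-0.05 to -0.35). The flagellum then had 0 rises and 12 falls (-0.18), alginate synthesis 5 rises (0.49), RND efflux 6 rises (0.28) and phenazine synthesis 1 rise and 4 falls (-0.02). Removal of a local background turned the flagellum from -0.07 to 0.05 and sulfur assimilation from -0.05 to 0.10, with 1 rise and 2 falls. The median of all genes left was then 0.29 and 0.37 in the AgNP 25 pair. With the running median along the chromosome removed, type III secretion had 0 rises and 1 fall with a median of -8.51e-05, and pili 0 calls with a median of -0.18. The flagellum turned to 0.11 with 6 rises and 1 fall, phenazine synthesis to 0.08 with 0 calls, and sulfur assimilation had 0 rises and 2 falls. Several small regulatory RNAs under 200 nt stood far below the control at AgNP 25. The iron-regulated RNAs prrF2 and prrF1 fell from 1615 and 605 FPKM to 35.7 and 46.7 and to 42.7 and 30.7 FPKM. The RNA rsmY fell from 35105 to 89.8 and 97.8 FPKM, rsmZ from 6301 to 0 and 94.9 FPKM, and phrD was listed at 28213 in the control and at 0 in all 4 AgNP libraries. PA4406.1 and PA1030.1 were listed at 2845 and 1749 FPKM in the control and at 0 in all 7 silver libraries.

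In all, 2601 of 5608 genes differed between AgNP 25 and the control at an adjusted p below 0.05, 1481 higher and 1120 lower, and 828 of them also changed at least 2-fold, 573 up and 255 down. Adjusted p-values of the named genes reached from 9.16e-22 for PA4406.1 to 2.91e-05 for dnaK. Adjusted over the list alone, 13 copper genes, 11 pyochelin genes, 18 pyoverdine genes, 15 quorum sensing genes, 10 Pf4 genes and 48 ribosomal genes were called. The same way, 7 zinc and cadmium efflux, 15 Zur, 15 oxidative stress, 8 heat shock, 6 iron-sulfur, 2 phenazine, 15 denitrification, 11 Anr, 7 type III, 18 type VI, 9 RND, 2 lipopolysaccharide, 14 Psl and Pel, 2 alginate, 2 flagellum, 5 pilus, 11 NADH dehydrogenase and ATP synthase, 9 terminal oxidase, 16 TCA, 14 sulfur, 7 phosphate, 9 SOS and 23 pyocin genes were called. The spread behind these tests came from 1 pair of libraries, whose own difference passed 2-fold in 24 genes, against 832 and 921 for each of them alone against the control. The count fell to 815 with the running median along the chromosome removed and to 1 with AgNP 20 pooled into the group. It was 750 with a local background removed, 580 higher and 170 lower. That removal leaves fewer genes, whose own median change was 0.29 and 0.37 in the pair.

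**Figure D3:**
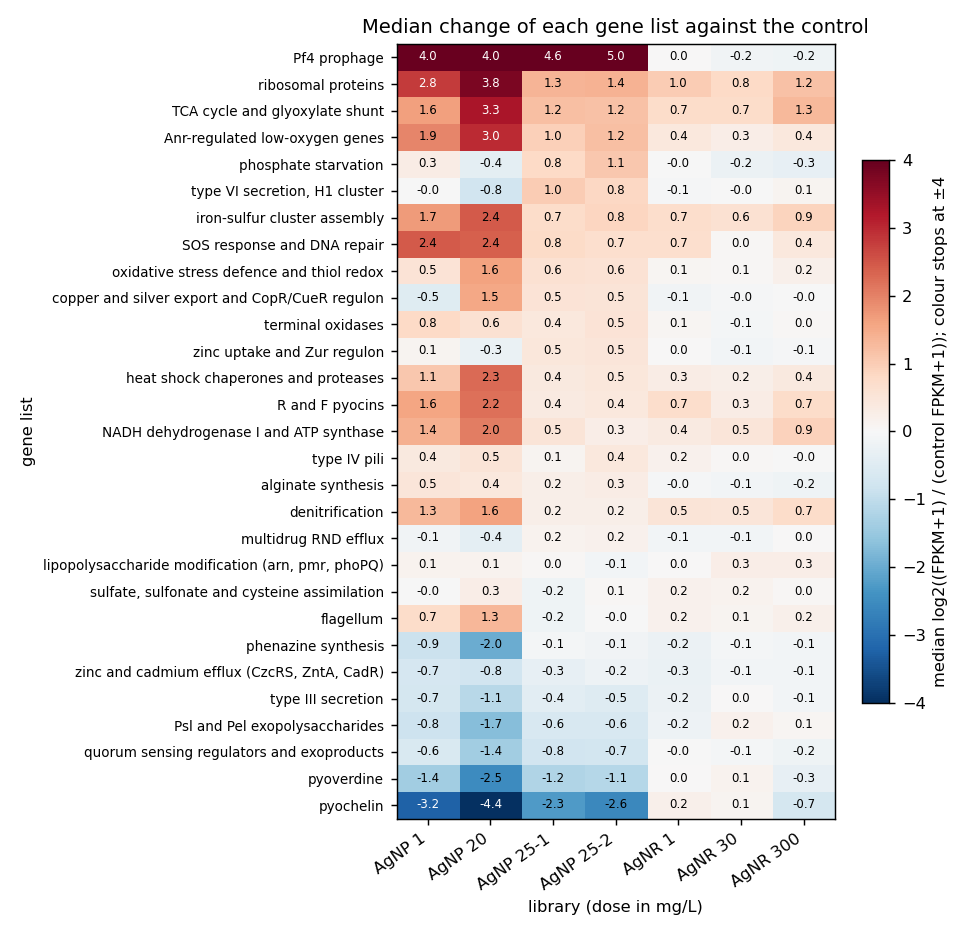
Median log2((FPKM + 1)/(control FPKM + 1)) of each of the 29 gene lists (rows, ordered by their mean at AgNP 25) in each silver library (columns, dose in mg/L), printed in each cell, with colours that stop at 4 and -4. Pf4 stands at 4.58 and 4.98 in the AgNP 25 pair and at -0.17 in AgNR 300, and pyochelin at -2.26 and -2.57 and at -0.70.

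Lower particle doses shared some of these differences and not others. The AgNP 1 and AgNP 20 columns appear recomputed, and those of the control and AgNP 25 do not. Dose and type of column therefore cannot be told apart where these doses are set against AgNP 25 or the control. Across genes AgNP 20 correlated more with AgNP 1 (Pearson r 0.917) than with the AgNP 25 pair (0.821 and 0.847). Pf4 was already high at AgNP 1, where coaB stood at 39190 FPKM, and reached 83379 FPKM at AgNP 20. The metal gene PA3920 was not higher at AgNP 1, at 35.2 FPKM against 41.7 FPKM in the control, and stood at 5143 FPKM at AgNP 20. PA3574a was already higher at AgNP 1, at 108 FPKM against 27.2 FPKM in the control, and stood at 19519 FPKM at AgNP 20. Pyochelin medians were log2 -3.25 at AgNP 1 and -4.39 at AgNP 20, pyoverdine medians -1.38 and -2.53, and bfrB stood at 1121 and 9422 FPKM. SOS genes had medians of 2.44 and 2.40, against 1.07 and 1.74 for matched lists, and ribosomal protein genes of 2.79 and 3.77, against 2.18 and 3.40. Matched medians were 0.87 and 1.39 for pyochelin and -0.60 and -1.04 for pyoverdine. The copper list had a median of -0.49 at AgNP 1, at percentile 0.875 of matched lists, and of 1.54 at AgNP 20, at percentile 100. Other lists stood apart from AgNP 25 at AgNP 20, where type VI secretion had a median of -0.77, phosphate starvation -0.38, phenazine synthesis -1.98 and the flagellum 1.32, against 0.37, -0.01, -0.54 and 0.55 for matched lists.

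Without replicates these doses had no test, and the AgNP dose line below joins both types of column. At least 2-fold differences from the control were seen in 1512 genes at AgNP 1 (1026 higher, 486 lower) and in 3037 genes at AgNP 20 (1635 higher, 1402 lower). Quantile normalization lowered these counts to 754 (398 higher, 356 lower) and 1196 (616 higher, 580 lower). With a local background removed the splits were 1398 higher and 109 lower at AgNP 1, and 1902 higher and 134 lower at AgNP 20. The median log2 difference of all genes left was then itself 1.15 and 1.90, which tilts both splits upward. Along the AgNP dose, limma called 0 of 5608 genes, and 752 had an unadjusted p under 0.05. The steepest rising lines, which did not pass, were those of PA3574a with a log2 slope of 1.53 (SE 0.22, adjusted p 0.105), PA3920 with 1.38, PA0720 with 1.29 and coaB with 1.27, and the steepest falling line was that of phrD with -2.54. The trend count was 539 without AgNP 20, 26 without AgNP 1 and 0 without each of the other libraries. Quantile normalization gave 256, and removal of a local background 17. Adjusted over the list alone, 10 copper genes had a rising slope and 1 a falling one, 9 Pf4 genes, 4 Zur genes, 1 TCA gene and 1 zinc and cadmium efflux gene had a rising slope, and 16 pyoverdine, 8 pyochelin, 10 quorum sensing genes and 1 denitrification gene had a falling one. The other lists had 0.

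As groups, 16 of the 29 lists had an AgNP slope apart from other genes under the preset correlation, 11 up and 5 down. The 5 down were pyoverdine (adjusted p 5.07e-10), pyochelin (1.49e-06), quorum sensing (4.40e-08), type III secretion (0.00563) and Psl and Pel (1.33e-05). The 11 up were Pf4 (4.40e-08), copper and silver export (9.20e-07), TCA cycle (1.85e-05), ribosomal proteins (5.58e-05), type VI secretion (0.00158), Zur (0.0103), NADH dehydrogenase and ATP synthase (0.0134), Anr (0.0135), heat shock (0.0418), phosphate starvation (0.0418) and SOS (0.0461). With an estimated correlation 0 of 29 lists were called, with adjusted p = 0.502 for quorum sensing, 0.739 for pyoverdine, pyochelin, Psl and Pel, Pf4 and copper and silver export, and 0.760 for the other 10 lists. Of the 16, the median slopes of heat shock (percentile 44.0), SOS (57.5), type III secretion (67.7), NADH dehydrogenase and ATP synthase (68.2), ribosomal proteins (90.3), Anr (96.0) and Psl and Pel (4.44) lay inside the middle 95% of matched lists. Lists whose median and mean slopes differed in sign, zinc and cadmium efflux (-0.06 and 0.02) and lipopolysaccharide modification (-0.01 and 0.01), were not called.

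**Figure D4:**
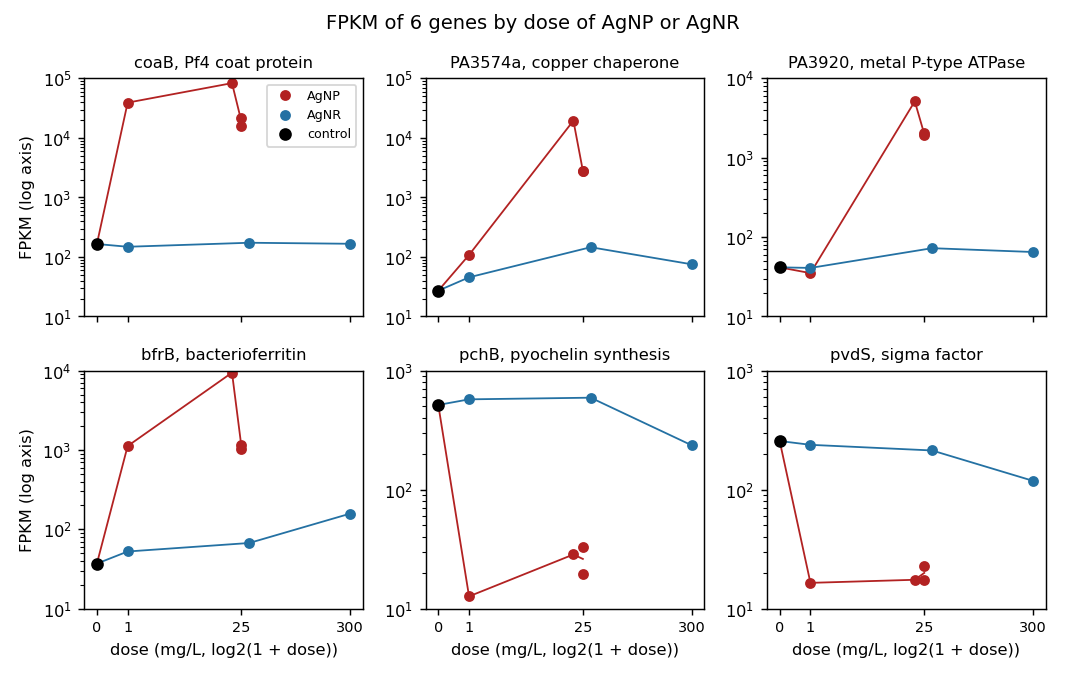
FPKM (vertical log axis) of coaB, PA3574a, PA3920, bfrB, pchB and pvdS by dose (horizontal axis, log2(1 + mg/L)), with AgNP in red, AgNR in blue and the control in black, where each point is 1 library and lines join the mean at each dose. The red points of coaB lie between 16061 and 83379 FPKM and its blue points between 148 and 173 FPKM.

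Nanorod libraries had fewer genes at least 2-fold from the control than AgNP libraries. At AgNR 300 metE (PA1927, positions 2106580 to 2108880), which encodes cobalamin-independent methionine synthase, stood at 303 FPKM against 54.7 in the control, log2 2.45 higher. The next largest were bfrB at 158 against 37.0 FPKM (2.06), sucD and sucC for succinyl-CoA ligase (1.77 and 1.76), and fhp for flavohemoprotein (1.76). The lowest against the control were PA4406.1 and PA1030.1, both listed at 0, then prrF2 at 99.2 against 1615 FPKM (-4.01) and prrF1 at 53.1 against 605 FPKM (-3.49). Of Pf4, coaB stood at 167 against 165 FPKM. Of the metal genes, named here outside the rule, PA3920 stood at 65.0 against 41.7 FPKM, PA3574a at 75.4 against 27.2 FPKM and oprC at 28.4 against 77.5 FPKM.

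By list, the median log2 difference of AgNR 300 from the control was 1.29 for the TCA cycle, 1.16 for ribosomal proteins and 0.93 for NADH dehydrogenase and ATP synthase, each at percentile 100 of matched lists. It was -0.70 for pyochelin and -0.32 for pyoverdine, both at percentile 0, with pchB at 236 against 515 FPKM and pvdS at 119 against 256 FPKM. Quorum sensing stood at -0.18 (percentile 0.23), denitrification at 0.73 (percentile 99.9), oxidative stress defence at 0.21 (percentile 80.0), SOS at 0.42 (percentile 82.1) and copper and silver export at -0.03 (percentile 32.1), which quantile normalization turned to 0.06. That normalization also took pyochelin to -1.40, quorum sensing to -0.32, ribosomal proteins to 0.58, denitrification to 0.43 and oxidative stress defence to 0.07. Removal of a local background took quorum sensing to -0.62, SOS to 0.72 and oxidative stress defence to 0.54. It left 9 quorum sensing and 14 oxidative stress members, and the median of all genes left was 0.32. Within the oxidative stress list katA stood at 275 against 82.2 FPKM, sodB at 354 against 114 FPKM and sodM at 108 against 271 FPKM. The ribosomal and TCA medians were 1.02 and 0.74 at AgNR 1 and 0.78 and 0.72 at AgNR 30, and those of pyochelin 0.19 and 0.12. At AgNR 30 metE stood at 297 FPKM and PA3574a at 146 FPKM. The largest difference upward at AgNR 1 was that of PA2754a, at 69.5 against 19.6 FPKM, and metE stood at 175 FPKM.

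At least 2-fold differences from the control were seen in 91 genes at AgNR 1 (77 higher, 14 lower), 40 at AgNR 30 (28 higher, 12 lower) and 195 at AgNR 300 (152 higher, 43 lower), against 24 between the AgNP 25 replicates, and none of them was tested. Quantile normalization raised the AgNR 30 count to 102 and turned the split at AgNR 1 to 30 higher and 39 lower and at AgNR 300 to 120 higher and 127 lower. Removal of a local background gave 174, 107 and 355 genes. Along the AgNR dose limma called 0 of 5608 genes, with 17 at an unadjusted p under 0.05, and 23 when the AgNR series was fitted alone with the control. The steepest lines, which did not pass, were those of phrD (log2 slope 0.40) and, downward, of PA4406.1 (-0.71) and PA1030.1 (-0.67). Under the preset correlation 10 lists had an AgNR slope apart from other genes, with adjusted p-values from 1.12e-05 to 0.0372. Copper and silver export, type III secretion, lipopolysaccharide modification, Psl and Pel, and the TCA cycle went up, and alginate synthesis, type IV pili, phosphate starvation, SOS and Pf4 down. Of these, type III secretion (percentile 88.0) and pili (5.22) lay inside the middle 95% of matched lists. With an estimated correlation there were 0, with adjusted p-values from 0.797 to 0.992, and adjusted over the list alone 0 genes were called in every list. The shared intercept of this fit is also set by the AgNP libraries, and the negative AgNR slope of coaB (-0.30) goes with AgNR values between 148 and 173 FPKM and a control of 165 FPKM. In the same way the rising AgNR slope of phrD goes with 19923, 21387 and 9278 FPKM, all below the control.

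The comparison of AgNP 25 with AgNR 30 set the nearest doses above 1 mg/L of the 2 forms side by side, though the doses differ. Pf4 genes were far higher with particles, with log2 differences of 6.77 for PA0720, 6.73 for coaB and 6.34 for PA0719 (SE 0.18 to 0.22). PA3920 was higher by log2 4.76 (SE 0.18), recN by 2.34 and arcB by 3.06. The pyochelin gene pchB was lower by log2 -4.49 (SE 0.24) and pvdS by -3.37, and so were the small RNAs phrD, rsmZ and rsmY. In the lists, 10 of 13 Pf4 genes were higher, and of 21 copper genes 11 were higher and 2 lower. All 11 pyochelin, all 18 pyoverdine and 15 of 24 quorum sensing genes were lower. Of the ribosomal protein genes 34 of 54 were higher and 3 lower, with a median of 0.60 against 0.55 for matched lists. The counts adjusted over the list alone were 10 for Pf4, 14 for copper, 11 for pyochelin, 18 for pyoverdine, 15 for quorum sensing and 37 for ribosomal proteins.

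limma called 2792 genes in this comparison, 1473 higher and 1319 lower with particles, and 895 of them also differed at least 2-fold (559 up, 336 down). The AgNR 30 column is 1 of the 5 that appear recomputed and the AgNP 25 columns are not. Silver form and type of column therefore cannot be told apart here. Each AgNP 25 library alone differed at least 2-fold from AgNR 30 in 926 and 1002 genes. The count fell to 778 with the running median along the chromosome removed, where the split turned to 367 higher and 411 lower, and to 589 with a local background removed. At the matched dose of 1 mg/L, for which there was no test, 923 genes differed at least 2-fold, 685 higher and 238 lower with AgNP, and 392 after quantile normalization, where the split turned to 181 higher and 211 lower. There coaB stood at 39190 FPKM with AgNP 1 and 148 FPKM with AgNR 1, and PA0722 at 10156 and 102 FPKM. The pyochelin median was lower by log2 -3.46 and the SOS median higher by 1.75.

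The test of whether AgNP and AgNR slopes per log2 unit of dose differ called 11 genes, 9 with the higher slope for AgNP. They included PA3574a with a slope difference of 1.34 (SE 0.20), PA3920 with 1.21 (SE 0.14), and PA3690 with 0.77, all annotated in metal transport or binding, PA3523 of an efflux pump with 0.78, and oprC, the gene of a copper-related outer membrane porin (PA3790, 4247703 to 4249874), with 0.87. PA4878, a transcriptional regulator gene, had 1.00. The genes with the lower slope for AgNP were kdpF (-0.51) and PA2312a (-0.54). Each had an adjusted p of 0.0472, and 1434 genes had an unadjusted p under 0.05. The 11 genes are all those called, outside the rule for named genes.

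This call was fragile. In simulated data where 200 genes were given an AgNP slope, 5 of the unchanged genes were also called. That is not a count for data without any change. The count was 0 without the control, without either AgNP 25 library or without any 1 of the AgNR libraries, and 189 without AgNP 1 and 1150 without AgNP 20. It was 0 with a pseudocount of 0.1, without the intensity trend, with dose as a rank or without genes under 200 nt, and 36 with a mean filter of 20, 82 with a local background removed and 928 after quantile normalization. As groups, 18 lists differed in slope under the preset correlation, 12 up and 6 down, with adjusted p-values from 5.11e-09 for pyoverdine to 0.0467. The 12 up were copper and silver export, Zur, heat shock, Anr, type VI secretion, alginate, pili, ribosomal proteins, TCA cycle, phosphate starvation, SOS and Pf4, and the 6 down pyoverdine, pyochelin, phenazine, quorum sensing, type III secretion and Psl and Pel. With an estimated correlation 0 were called, with adjusted p-values from 0.695 to 0.938. Of the 18, type III secretion (percentile 54.3), ribosomal proteins (80.4), type VI secretion (84.2), the TCA cycle (90.6), Anr (92.9), heat shock, pili and SOS lay inside the middle 95% of matched lists. Adjusted over the list alone, 11 copper, 10 Pf4, 5 Zur, 4 phosphate, 3 Anr, 2 TCA genes and 1 zinc and cadmium efflux gene had the higher slope for AgNP. The lower slope was called in 18 pyoverdine, 11 pyochelin, 12 quorum sensing and 9 Psl and Pel genes and in 1 gene each for copper export, zinc and cadmium efflux and denitrification.

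Genes that changed in both forms were counted to see whether the responses overlap. Of the 573 genes up at least 2-fold and called at AgNP 25 and the 152 up at least 2-fold at AgNR 300, 108 were shared, against 15.5 for independent sets. Of 255 and 43 down, 33 were shared, against 1.96, and 4 genes went opposite ways. Because 1 control served both, changes share its error. Simulated unchanged libraries against a single control shared 0.33 genes up and 0.30 down. Their correlation of changes across genes was 0.577 against 0.496 in the data, and their covariance 0.0306 against 0.197. The simulated control was given the spread of the group fit, which rests on the AgNP 25 pair. A control with more error than that would share more, so the simulation cannot show that the overlap exceeds shared error. With different references, AgNP 25 against AgNP 1 and AgNR 300 against AgNR 1, 3 genes were shared up and 4 down, against 0.595 and 3.57 for independent sets, while 12 went opposite ways, with a correlation of 0.04 and a covariance of 0.00918. Genes are not independent replicates, and no p-value was attached to these values.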

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

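The tests on recomputed columns, on a background floor in the control and on whole-prophage copies were chosen after the values they measure had been seen, and the removal of a local background and of the running median were alternatives added after the data were seen. So were further readings of planned tests, namely the share of genes with at least 10 FPKM left after background removal, the gradient against its steepest group of genes and in AgNP 25 values alone. The test of genes that stay lower after background removal, the 4 list tests on position, the test on genomic DNA and the count over other assignments were written before their results were seen.

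The slopes of 11 genes differed between AgNP and AgNR in the test of the difference itself. Per log2 unit of dose the AgNP slope minus the AgNR slope was 1.34 for PA3574a, 1.21 for PA3920, 1.00 for PA4878, 0.87 for oprC, 0.78 for PA3523, 0.77 for PA3690, 0.77 for PA0508, 0.40 for PA0278, 0.37 for betA, -0.51 for kdpF and -0.54 for PA2312a. When shape and dose were reassigned among the 7 silver libraries, 8 of 100 assignments, the real one included, called as many genes, so chance is not excluded for a count of 11. The highest other assignment called 2391 genes, which points to a structure of the samples, and what that structure is was not tested. No gene list was called with both the preset and the estimated correlation, so none was raised here.

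Signal was also present in genes that the comparisons did not use because the control was listed at 0 and the recomputed columns held errors there. PA0721, a 92 nt gene inside Pf4 (positions 790617 to 790709), stood at 6528 FPKM in AgNP 25 replicate 1 and at 4238 FPKM in replicate 2. PA3304.1 stood at 12.3 FPKM and PA4060 at 1.43 FPKM in AgNP 25 replicate 1, and both at 0 in replicate 2.

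Values were packed more narrowly in the control and AgNR libraries than in the AgNP libraries. The narrowest recomputed AgNP column was wider than the widest recomputed AgNR column by 0.75 log2 units. This argues against a recomputation that set the spread alike in all 5 columns. A formula that put each gene on the scale of the listed control could still pass on its narrow spread to libraries with little change. For the AgNR columns recomputation therefore stays open. Whether an additive background in the control contributed stays open. The 1122 genes lowest in AgNP 20 had a median control value of 0.720 of the control median, but 0.381 of the median in AgNP 1. That comparison cannot decide it, because the narrow control spread fixed its outcome. Even the 5th percentile of the control was 21.2 FPKM, against a median of 39.8 FPKM. Whether such a background could be the whole cause for genes lower in AgNP 20 stays open too. After a local background was taken off both libraries 60.9% of them, 854 of 1402, stayed at least 2-fold lower, but a gene with little signal left passes that test easily. Only 509, or 36.3%, also kept at least 10 FPKM in the control. The AgNP 20 fold count with that background removed and low genes left out had 134 lower and 1902 higher genes. The median log2 difference of the genes left was itself 1.90 there, so that split cannot decide the question. A difference between the silver forms, and differences between library preparations that the labels do not record, stay open and untested.

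Pf4 genes were high in the AgNP libraries and near the control in the AgNR libraries. The lowest median over the list in a recomputed AgNP column exceeded the highest in a recomputed AgNR column by 3.96 log2 units. This argues against a recomputation that acted alike on all 5 columns. If the AgNR values were put on the scale of the listed control, their Pf4 levels could follow that control, and this stays open. Whether there were more copies of the whole prophage genome stays open. At AgNP 25 and AgNP 1 the 4 measured genes outside PA0718 to PA0727 had median log2 differences from the control of 0.16 and 0.24. The genes inside stood higher by at least 4.67 and 3.87. RNA was thus not raised alike over the whole prophage at these doses. This cannot decide on copies, because RNA of the outer genes need not follow them and the outer set was drawn after its values were seen. At AgNP 20 the outer genes had a median of log2 2.01, from -0.10 for PA0728 to 3.29 for PA0729. A hypothesis that remains is that transcription of the inner Pf4 genes may follow particle exposure, but AgNP and AgNR cultures could also have differed in their share of cells with active phage before exposure, which these data do not test.

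At AgNP 25 changes against the control depended on distance from the replication origin. Position may account for 4 lists. With the running median taken off their median log2 changes were -0.0319 for type VI secretion, -0.00863 for phosphate starvation, 0.0378 for zinc uptake and -0.0601 for Psl and Pel. All lay inside the middle 95% of random lists of the same size, which were not matched on expression. Medians of some lists not named in advance for this test also moved close to 0. They were -8.51e-05 for type III secretion (from log2 -0.48), -0.01 log2 units for the pyocins (from 0.39) and -0.02 for zinc and cadmium efflux (from -0.26). The 4 lists kept 0 calls, but the pyocins kept 5 rises and 6 falls, zinc and cadmium efflux 2 rises and type III secretion 1 fall. Genomic DNA read in the libraries would show mostly in weakly expressed genes, and it stays open as a cause of the gradient. The gradient in the 1120 genes highest in AgNP 20 was 1.02 times that in the 1128 lowest (-0.278 and -0.273 log2 units per Mb), but 0.613 times that in the steepest group, the next lowest 1120 genes (-0.454). The bound of 0.75 set in advance for excluding it was wrong for a fold, since the control's own gradient, which is taken off, was -0.185 in the lowest genes and -0.033 in the highest. In the AgNP 25 values themselves the ratio of highest to lowest was 0.680, below that bound. A difference in growth or replication between the cultures, which would change gene dosage along the chromosome, stays open and untested.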

How the results depend on the processing

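Removal of a local background, removal of the running median and exclusion of genes under 200 nt were chosen after seeing the data, as were single AgNP 25 libraries against AgNR 30, and the causes of the shifts were not tested unless stated. The AgNP 25 against control and AgNP 25 against AgNR 30 counts stayed within 1.5 times under both other pseudocounts, both other filters, both other scalings, moderation without trend and the fit of only the 2 groups. With AgNP 20 pooled into AgNP 25 the first called 1 gene. With the running median removed they were 815 and 778. Without AgNP 25 replicates in turn, where a 2-fold count replaced the test, they ranged from 832 to 921 and from 926 to 1002.

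Removal of a local background, which left 2551 genes, gave 750 for AgNP 25 against control, 589 for AgNP 25 against AgNR 30, 17 for the AgNP trend, 82 for the slope difference, and 174, 107 and 355 for AgNR 1, AgNR 30 and AgNR 300. Under it the median change of all genes lay between 0.23 and 1.90 log2 units. With the mean filter of 20 that median reached 0.25 at AgNP 20, against 0.06 there in the main setting. With the local background removed 6 lists were called for the AgNP slope and 6 for the slope difference. Quantile normalization gave 256 for the AgNP trend, 928 for the slope difference, 754 for AgNP 1, 1196 for AgNP 20, 102 for AgNR 30 and 392 for AgNP 1 against AgNR 1. The slope difference count was also 0 with a pseudocount of 0.1, without trend, with dose as a rank or without genes under 200 nt, and 36 with a mean filter of 20. The AgNR trend fitted on its series alone called 23. Leaving out each library in turn gave 0 to 539 for the AgNP trend, 0 to 0 for the AgNR trend and 0 to 1150 for the slope difference. With an estimated correlation 0, 0 and 0 lists were called for the AgNP slope, the AgNR slope and their difference. The depth behind each value is unknown and limits what can be said of genes near 0.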

Other observations

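Small RNAs that no list held were read after their values were seen. The RNA crcZ, which binds the protein Hfq in carbon catabolite repression (positions 5308587 to 5308993), stood at 5654 FPKM in the control, 36252 at AgNP 1, 150425 at AgNP 20, 16910 and 15074 at AgNP 25, 10278 at AgNR 1, 7584 at AgNR 30 and 10083 at AgNR 300. Its AgNP 25 change against the control was log2 1.50 (SE 0.28, adjusted p 0.000331 in the limma group fit). The annotated RNA PA4726.2 overlaps it, so the values of both are uncertain. The RNA phrS stood at 2597 FPKM in the control, 1768 at AgNP 1 and 18976 at AgNP 20, and the 6S RNA gene ssrS at 46462, 47433 and 355676 FPKM. Highly expressed genes were widely higher at AgNP 20, where random lists matched to ribosomal protein genes had a median log2 difference of 3.40. Neither RNA passed the limma group test at AgNP 25 (log2 0.34, adjusted p 0.194, and -0.47, adjusted p 0.291).

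The prrF RNAs lay between control and AgNP levels at AgNR 1 and AgNR 30, and at AgNR 300 prrF1 lay within the AgNP range. In that series prrF1 stood at 278, 220 and 53.1 FPKM and prrF2 at 534, 387 and 99.2 FPKM from AgNR 1 to AgNR 300. The RNA rsmZ stood at 3730, 3532 and 1651 FPKM and phrD at 19923, 21387 and 9278 FPKM in the same libraries. These are single libraries without a test, and all 4 genes are under 200 nt.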
